A study of Macaca mulatta with 24 samples.

How the data were processed

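RNA sequencing was done on airway epithelial cells of the trachea and bronchi, cultured from adult female rhesus macaques and differentiated on porous inserts at an air–liquid interface, with retinoic acid in the medium. Cultures of 4 animals (S1 to S4) were exposed to whole wood smoke, diluted, or to filtered air, in sessions of 6 hours on each exposure day. In the order S1 to S4, the animals were 5463, 2930, 2238 and 1128 days old and weighed 5.59, 7.17, 4.56 and 3.18 kg. Each age belonged to 1 animal, so age and animal cannot be told apart. The 6 groups were air and smoke after 1 day, after 5 days, and at the end of a recovery week (7 days) that followed 5 days of exposure, with 1 library per animal in each group and 24 libraries in all. Per the labels, libraries were prepared from poly-A selected RNA, and the processing notes name FastQC, Trim Galore, Bowtie2 and RSEM, with versions not given. The genome build, the annotation release and the tool that normalized the table are not given in the sources used here, so no chromosome positions are printed.

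The deposited table holds a normalized signal per gene and library, called normalized counts below, although the table is named as raw counts. The values are not whole numbers, and the median ratio of each library to the geometric mean over libraries was 1.01 in every library, as division by a library size factor gives. Among low values, 76.7 to 82.9% per library were whole multiples of a step that differed between libraries, within 0.1 of the step, so whole reads were not recovered. The step, taken as the value of 1 read, ranged from 0.727 to 1.61, and dividing the totals by it gave approximate depths of 9.45 to 17.4 M reads per library. Tests written for whole counts were therefore not used. Counting error cannot be computed from these values, and the precision of each value is given as the spread between animals.

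The table has 35432 genes, of which 23817 carry a symbol and 720 more took theirs from the gene name table of the reference. Values were analysed as log2(value + 1). Genes with a value of at least 10 in at least 4 libraries were tested, 14062 in all. Group means were fitted to all 24 libraries with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean (trend), without a block, and 7 contrasts were tested, two-sided: smoke against air at each of the 3 times, the change of the smoke effect from 1 day to 5 days and from 5 days to recovery, and air over the same intervals. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the genes tested were called, and every adjusted p below is from limma unless another test is named. The design fixed before the data were examined had named edgeR with TMM scaling, and limma on the log2 values replaced it when the values proved not to be counts. The libraries of each animal were pairs by label and in the data: deviations from group means correlated at 0.303 to 0.804 (median 0.612, 60 pairs) between libraries of the same animal and at −0.443 to 0.0149 (median −0.189, 180 pairs) between animals. The fit with animal as an additive block was also fixed in advance, and its values stand beside the results as "with animal as a block".

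Genes were named by a rule fixed before the data were examined. It takes the 10 largest changes in each direction at each time among genes with a symbol, an average of at least 1 CPM and an adjusted p under 0.05 that changed the same way in all 4 animals, with places left filled from the fit with animal as a block. It takes the 5 largest for each other contrast, the 4 members with the smallest p from each gene list, the 5 persistent genes in each direction with the smallest recovery p, and 10 genes always given, of which MUC5AC had no match in the table. Some genes that the rule names are not reported here. The 24 gene lists were fixed at the same time from textbook knowledge and matched by symbol. An earlier match that also accepted the reference symbol where the table gave another was replaced after its list results had been seen, and is kept as an alternative. Lists were tested with limma camera (preset correlation 0.01, p adjusted over the 24 lists within a contrast), with an estimated correlation as the alternative. CYP1A1 was below the filter and was compared by an exact permutation test of 4 against 4 libraries (70 assignments, smallest p 0.0286, two-sided), adjusted over the 3 times. Library measures were compared by the same test, adjusted over 12 tests. This permutation test ignores the pairing by animal, and exact sign flips by animal can give no p under 0.125 for CYP1A1 or for these measures.

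Alternatives fixed in advance were the block, the block as a random effect, only the libraries of a contrast with and without the block, library totals as the only scaling, no filter, a stricter filter (1 CPM in 4 libraries), an adjusted p of 0.1, an added log2 fold change of 1, and leaving out each animal and each library. Added after the data were seen were pseudocounts of 0.5 and 5, quantile normalization, no variance trend, array weights with the block, the block with an estimated correlation, and the block without the 5-day air library of S1. Each fit was tested on simulated data made by adding changes to 200 genes: a fold of 2 was recovered for 44 to 50% of genes without a block and for 61 to 69% with it, and 0 to 2 and 8 to 11 other genes were called. Gene spans came from the reference annotation, matched by symbol for 12101 genes (86.1% of those tested). No library and no column was left out of the comparisons unless stated. Figures were drawn with matplotlib 3.10.9.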

Results

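The data were normalized read counts of 35432 genes in 24 libraries of macaque airway epithelial cultures, with 4 animals in each of 6 groups. Normalized totals ranged from 11.8 M (air, 1 day, S1) to 15.2 M (air, 5 days, S1), and approximate depths from 9.45 M reads (air, 5 days, S1) to 17.4 M (air, 1 day, S4). Between 12927 and 13255 genes per library had a value of 10 or more. The share of values in the 13 mitochondrially encoded genes ranged from 2.95 to 8.82%, and the share in the 10 most abundant genes from 15.0 to 22.9%. No measure of library composition passed a test of smoke against air after adjustment over 12 tests. The lowest p was that of approximate depth at 5 days (14.4 ± 1.30 M reads in smoke against 11.8 ± 1.56 M in air, SD, n = 4, exact permutation p = 0.0286, adjusted p = 0.343). The 5-day air library of S1 stood apart, with a median correlation to the other libraries of 0.860 against 0.931 to 0.956 for the other 23.

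**Figure D1:**
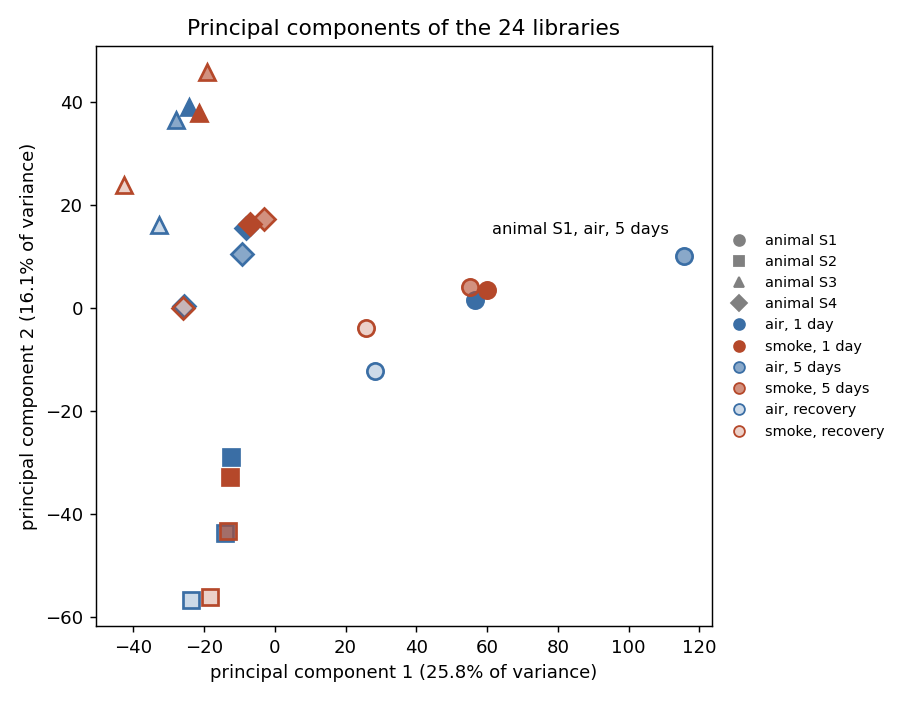
Principal components 1 (25.8% of variance) and 2 (16.1%) of the log2 values of the 24 libraries, which have no unit. Marker shape gives the animal, colour the exposure and shading the time. Libraries lie near others of their animal, and the 5-day air library of S1 lies farthest to the right.

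The first comparison asked what a single 6-hour exposure to wood smoke did. After 1 day, CYP1B1 (ENSMMUG00000013945), a cytochrome P450 that metabolizes polycyclic aromatic hydrocarbons and is induced through the aryl hydrocarbon receptor (AHR), rose 7.08-fold, from 233 ± 57.9 normalized counts in air to 1677 ± 513 in smoke (SD, n = 4). Its log2 fold change was 2.82 ± 0.30 (SE, adjusted p = 6.1e-05), and it was higher in 4 of 4 animals. CYP1A1, the classical AHR target, had few reads, with a median of 7.53 (2.23 to 60.6) in smoke against 0.854 (0 to 1.72) in air (higher in 4 of 4 animals, exact permutation p = 0.0286, adjusted p = 0.0429). The RNA-binding protein gene HNRNPDL also rose (log2 0.83 ± 0.15, adjusted p = 0.040), as did the kinase anchor gene AKAP17A (0.79 ± 0.13, adjusted p = 0.023) and WDR13 (0.70 ± 0.12, adjusted p = 0.023), each higher in 4 of 4 animals. No gene fell in the fit without a block.

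The lists gave 4 group changes at 1 day. The AHR response list rose (8 of 10 members above 0, mean log2 0.445 ± 0.875 SD, median 0.331, adjusted p = 4.79e-05, 0.00232 as an adjusted p with an estimated correlation), with CYP1B1 the member that passed on its own, also when adjusted over the list alone. The receptor's repressor AHRR was at log2 0.04 ± 0.15. The NRF2 oxidative stress response rose (24 of 26 members above 0, mean log2 0.223, adjusted p = 2.45e-07, adjusted p = 0.00232 with an estimated correlation). Its members include the antioxidant genes SRXN1 (0.39 ± 0.13), AKR1C1 (0.32 ± 0.13), PGD (0.29 ± 0.16) and HMOX1 (0.64 ± 0.43), and 0 of them passed on their own. Without a block the list did not pass at 5 days or after recovery (adjusted p = 0.561 and 0.550). At 5 days it passed with animal as a block and without the 5-day air library of S1 (adjusted p = 0.000968), but not with an estimated correlation as well (adjusted p = 0.385). Cholesterol biosynthesis rose (18 of 19 members above 0, mean log2 0.276, adjusted p = 3.45e-05). With an estimated correlation this call was lost without a block (adjusted p = 0.703) and kept with animal as a block (adjusted p = 0.0284). It was lost with the block when the 5-day air library of S1 was also left out (adjusted p = 0.162). SQLE, an epoxidase of the pathway, was at 0.48 ± 0.27. Heat shock and chaperone genes fell (12 of 14 members below 0, mean log2 −0.216, adjusted p = 3.45e-05, adjusted p = 0.030 with an estimated correlation). The small heat shock protein gene HSPB1 was at −0.50 ± 0.23, the mitochondrial chaperonin HSPD1 at −0.34 ± 0.12 and DNAJB4 at −0.37 ± 0.11. Adjusted over the list alone 2 members were lower and 1 higher. With animal as a block, 1 member was called over all genes, DNAJB1, and it was higher.

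In all, 4 of 14062 genes were called at 1 day (4 higher, 0 lower), against 265 with an unadjusted p under 0.05. With animal as a block 11 were called (8 higher, 3 lower). Without the 5-day air library of S1, which is not in this comparison, 15 were called without a block (6 higher, 9 lower) and 135 with it (54 higher, 81 lower), so the balance of directions depends on that library. Named places filled from the fit with the block went to KLF6, an early-response transcription factor gene (log2 1.49, adjusted p = 4.0e-08), and to RHOB (1.04, adjusted p = 0.00040). The splicing factor gene SRSF5 (0.53, adjusted p = 0.029) also was higher in that fit, as was DNAJB1 (0.42, adjusted p = 0.016), a cochaperone gene of the heat shock list. MEIS1 (−0.61, adjusted p = 0.0015) and the splicing kinase gene CLK1 (−0.48, adjusted p = 0.031) were lower. Only CYP1B1 kept its call in the fit without a block with each library or animal left out in turn. HNRNPDL, AKAP17A and WDR13 kept theirs in 2, 2 and 1 of 8 omissions of a single library.

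The comparison at 5 days asked what repeated exposure did. CYP1B1 was again higher, at 274 ± 85.3 normalized counts in smoke against 42.6 ± 15.4 in air (log2 2.65 ± 0.30 SE, n = 4, adjusted p = 9.1e-05). CYP1A1 lay at 2.87 to 7.86 in smoke against 0 to 1.05 in air (higher in 4 of 4 animals, exact permutation p = 0.0286, adjusted p = 0.0429). RSRP1 (ENSMMUG00000002970), an arginine- and serine-rich protein gene, fell 3.90-fold, from 612 ± 106 to 158 ± 41.8 (log2 −1.96 ± 0.20, adjusted p = 3.4e-05). The RNA helicase gene EIF4A2 (−0.73 ± 0.10, adjusted p = 0.0017), the RNA-binding protein gene HNRNPH3 (−0.62 ± 0.09, adjusted p = 0.0022) and NKTR (−0.59 ± 0.11, adjusted p = 0.043) fell, while HNRNPDL rose (0.80 ± 0.15, adjusted p = 0.033). The HSP90 cochaperone gene FKBP4 fell (−0.90 ± 0.14, adjusted p = 0.0054), as did the receptor tyrosine kinase gene EPHA2 (−0.44 ± 0.08, adjusted p = 0.015), and WDR13 rose (0.74 ± 0.12, adjusted p = 0.0059). All these changes had the same sign in 4 of 4 animals.

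As groups, heat shock and chaperone genes fell at 5 days (13 of 14 members below 0, mean log2 −0.343, adjusted p = 8.83e-06, adjusted p = 0.0466 with an estimated correlation). Of its members 0 passed over all genes and 6 were lower adjusted over the list alone. With animal as a block HSPB1 (−1.10, adjusted p = 0.021), the collagen chaperone gene SERPINH1 (−0.61, adjusted p = 0.017) and DNAJA1 (−0.49, adjusted p = 0.011) fell. The AHR response list rose (7 of 10 members above 0, mean log2 0.456, median 0.290, adjusted p = 0.0179), but not with an estimated correlation (adjusted p = 0.0867), nor with animal as a block without the 5-day air library of S1 (adjusted p = 0.185). The 4 other calls were all lost with an estimated correlation (adjusted p = 0.737 for each). They were higher cell cycle genes (21 of 21 members above 0, mean log2 0.596, adjusted p = 4.27e-05), with MKI67 at 1.53 ± 0.56 and AURKA at 0.98 ± 0.32, and lower hypoxia and glycolysis genes (17 of 18 measured identifiers below 0, mean −0.554, adjusted p = 0.00068). VEGFA (−0.58, adjusted p = 0.039) and P4HA1 (−0.72, adjusted p = 0.042) of these were lower with animal as a block. They also were higher multiciliogenesis regulators (12 of 14 above 0, mean 0.655, adjusted p = 0.00659), with GMNC at 1.32 ± 0.73, and lower immediate early and EGFR ligand genes (mean −0.278, adjusted p = 0.0436). In that last list FOS (−0.86, adjusted p = 0.016) and JUNB (−0.62, adjusted p = 0.023) were lower with animal as a block. Without the 5-day air library of S1 and with animal as a block, the median of the multiciliogenesis list went from 0.759 to 0.399 and that of the immediate early list from −0.259 to −0.118. The mean of the multiciliogenesis list was 1.46 in S1 against 0.103 to 0.757 in the other animals. With 1 animal left out, the immediate early list lost its call in 4 of 4 cases (adjusted p up to 0.143), and the AHR and multiciliogenesis lists theirs without S1 (adjusted p = 0.125 for each) and without S3 (adjusted p = 0.05 for each). The hypoxia list lost its call without S3 (adjusted p = 0.055). The cholesterol list rose only with animal as a block (adjusted p = 0.00512, 0.455 as an adjusted p with an estimated correlation), with INSIG1 at 0.70 (adjusted p = 0.028).

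At 5 days 10 genes were called (4 higher, 6 lower), 9 of them named above and 1 without a symbol, and 1306 had an unadjusted p under 0.05. Adding animal as a block, 237 were called (125 higher, 112 lower), and 880 (416 higher, 464 lower) with the block and without the 5-day air library of S1, which alone took the count without a block to 53. Places filled from the fit with the block went to 7 higher genes, among them TPH1 (2.18, adjusted p = 0.015), TXNRD3 (1.59, adjusted p = 0.0057) and GCFC2 (1.75, adjusted p = 0.0096). The lower ones were CELF4 (−1.48, adjusted p = 0.0084), TNNI2 (−1.36, adjusted p = 0.016), PPP1R3G (−1.34, adjusted p = 0.023) and CEACAM7 (−1.29, adjusted p = 0.039). In the fit without a block, 6 of the 9 named calls stayed in every omission of a single library. Only 2, CYP1B1 and RSRP1, stayed in every omission of an animal.

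**Figure D2:**
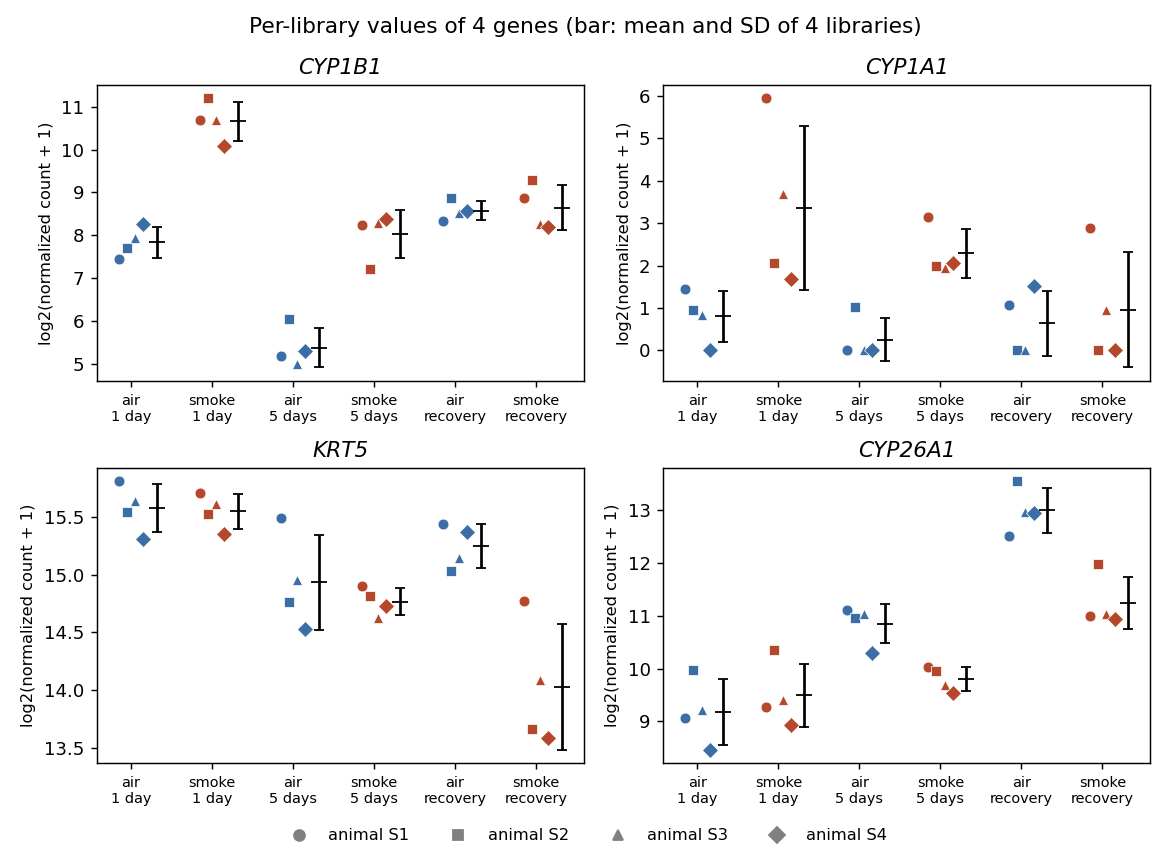
Log2(normalized count + 1) of CYP1B1, CYP1A1, KRT5 and CYP26A1 in each library by group, with the mean and SD of 4 libraries beside the points and marker shape giving the animal. CYP1B1 was higher in smoke in 4 of 4 animals at 1 and 5 days, and KRT5 and CYP26A1 were lower in smoke in 4 of 4 animals after recovery.

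The recovery comparison asked what remained 7 days after repeated exposure. Genes of basal cells, the progenitors of the airway epithelium, fell (12 of 12 measured members below 0, mean log2 −0.692, median −0.561, adjusted p = 2.11e-09, adjusted p = 0.000611 with an estimated correlation). The call was lost at an adjusted p = 0.102 with an estimated correlation, animal as a block and the 5-day air library of S1 left out, together. KRT5 (ENSMMUG00000055016), a keratin of basal cells, went from 39039 ± 5131 normalized counts in air to 17602 ± 7214 in smoke (log2 −1.22 ± 0.22 SE, n = 4, adjusted p = 0.017). The hemidesmosome integrin gene ITGB4 fell too (−1.04 ± 0.16, adjusted p = 0.0091). Of the list, 2 members passed over all genes and 5 adjusted over the list alone, and NGFR (−1.08, adjusted p = 0.0021), COL17A1 (−0.94, adjusted p = 0.0089) and LAMB3 (−0.48, adjusted p = 0.0046) fell with animal as a block. CYP26A1 (ENSMMUG00000010881), the enzyme that degrades retinoic acid, was 3.38-fold lower in smoke (2547 ± 1007) than in air (8478 ± 2591, log2 −1.76 ± 0.32, adjusted p = 0.017). Its level lay higher after recovery than at 5 days under both exposures. In smoke libraries it was 745 to 1044 at 5 days and 1971 to 4055 after recovery, and in air libraries 1255 to 2227 and 5890 to 12070. CYP1B1 did not pass (log2 0.07 ± 0.30), and CYP1A1 was higher in 2 of 4 animals (exact permutation p = 0.886).

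Further calls after recovery were TNS4 (−1.65 ± 0.30, adjusted p = 0.017), EMP1 (−1.30 ± 0.19, adjusted p = 0.0091), the cadherin gene CDH13 (−1.24 ± 0.25, adjusted p = 0.034), PLXNA2 (−1.19 ± 0.19, adjusted p = 0.010) and the desmosomal plakophilin gene PKP1 (−1.14 ± 0.19, adjusted p = 0.012). The transcription factor gene TFCP2L1 (−1.28 ± 0.20), the amino acid transporter gene SLC7A5 (−1.18 ± 0.22) and SIPA1L2 (−1.16 ± 0.20) also fell. ELMO1, which acts in engulfment and cell migration (1.31 ± 0.25, adjusted p = 0.021), SAP30 (1.23 ± 0.23, adjusted p = 0.019) and AGR3 (0.83 ± 0.16, adjusted p = 0.021) rose. With animal as a block the glycolysis regulator gene PFKFB4 (1.58, adjusted p = 0.0084), GPR146 (1.42, adjusted p = 0.013) and CRELD2, of the endoplasmic reticulum (0.95, adjusted p = 0.017), were among 7 more that rose.

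Of the other lists after recovery, 4 fell and each was lost with an estimated correlation in the fit without a block. Immediate early and EGFR ligand genes had 14 of 16 members below 0 (mean −0.645, adjusted p = 1.01e-07, 0.107 as an adjusted p with an estimated correlation). Among them EGR1 (−1.08, adjusted p = 0.0087), FOS (−0.79, adjusted p = 0.012) and FOSL1 (−1.86, adjusted p = 0.028) were lower with animal as a block. Mesenchymal and matrix remodelling genes had 14 of 14 below 0 (mean −0.779, adjusted p = 5.57e-05, 0.107 as an adjusted p with an estimated correlation). LOXL2 (−1.07, adjusted p = 0.019) of these fell with animal as a block. Cell cycle genes had 19 of 21 below 0 (mean −0.636, adjusted p = 3.54e-06, 0.534 as an adjusted p with an estimated correlation), with MKI67 at −1.86 (adjusted p = 0.012 with animal as a block). Squamous genes had 9 of 11 below 0 (mean −0.501, adjusted p = 0.015, 0.198 as an adjusted p with an estimated correlation), with the desmoglein gene DSG3 at −1.39 (adjusted p = 0.0089 with animal as a block). Motile cilium genes, which did not pass without a block (adjusted p = 0.209), rose with it (19 of 23 above 0, mean 0.242, adjusted p = 0.00432, 0.564 as an adjusted p with an estimated correlation). Their mean was 0.527 in S1 and 0.406 in S3, but 0.00955 in S2 and 0.0253 in S4. The goblet and club cell lists did not pass (adjusted p = 0.753 and 0.821).

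After recovery 34 genes were called (4 higher, 30 lower), and 1197 had an unadjusted p under 0.05. With animal as a block 480 were called (160 higher, 320 lower), which includes all 34, and 2639 (1224 higher, 1415 lower) with the block and without the 5-day air library of S1, whose omission lowers the pooled spread although it is not in this comparison (352 without a block, 131 higher and 221 lower). The count without a block rested on single libraries and animals. It was 88 without the smoke library of S1, 2 without that of S4, 476 without S1 and 0 without S4. Of 14 named calls EMP1 and ITGB4 alone stayed in every omission of a single library and 0 in every omission of an animal. These omissions were made in the fit without a block, which ignores the pairing, and were not run with animal as a block.

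**Figure D3:**
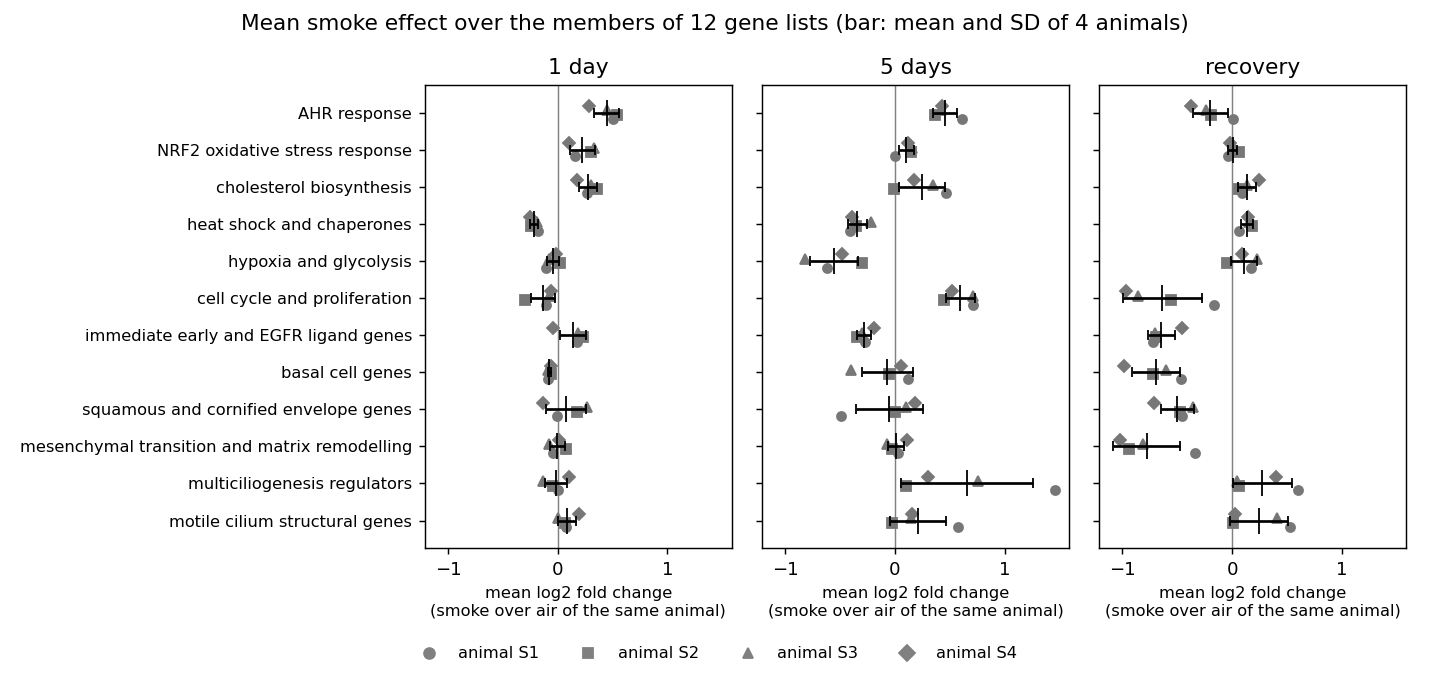
Mean log2 fold change of smoke over air of the same animal over the members of 12 gene lists at each time, with 1 point per animal, marker shape giving the animal, and the mean and SD of the 4 animals. Basal cell genes were below 0 in every animal after recovery (means −0.468 to −0.981), and heat shock genes were below 0 in every animal at 1 day and 5 days.

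The change of the smoke effect between times was tested directly. From 1 day to 5 days 2 genes changed, EPHA2 (difference of log2 fold changes −0.75 ± 0.11 SE, adjusted p = 0.0084) and AKAP17A (−1.07 ± 0.18, adjusted p = 0.046), and 513 had an unadjusted p under 0.05. Both lost their call without S2, S3 or S4, and AKAP17A kept its call in only 2 of 16 omissions of a single library. A block for animal gave 6, the other 4 being RGS2 (1.44, adjusted p = 0.018), RSRP1 (−1.58, adjusted p = 0.0017), KLF6 (−1.52, adjusted p = 1.1e-05) and GPRC5A (−0.83, adjusted p = 0.025). For CYP1B1 no difference between 1 and 5 days was detected (−0.18 ± 0.42). The effect on cell cycle genes moved up (adjusted p = 2.09e-05, 0.656 with an estimated correlation), as did that on multiciliogenesis regulators (adjusted p = 0.0256, 0.656 as an adjusted p with an estimated correlation). That on immediate early genes moved down (adjusted p = 0.0284, 0.656 as an adjusted p with an estimated correlation), and so did that on hypoxia genes (adjusted p = 0.0224, 0.791 as an adjusted p with an estimated correlation). With 1 animal left out, the changes for immediate early, multiciliogenesis and hypoxia genes each kept their call in 2 of 4 cases (adjusted p up to 0.177). The median change for multiciliogenesis regulators went from 0.777 to 0.409 with the block and without the 5-day air library of S1.

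From 5 days to recovery the smoke effect changed for 49 genes (20 up, 29 down), and for 501 with animal as a block (200 up, 301 down). The effect on RSRP1 moved up by 2.44 ± 0.28 (adjusted p = 0.00030), on SAP30 by 2.00 ± 0.32 (adjusted p = 0.0060), on CELF4 by 1.94 ± 0.42 (adjusted p = 0.043), on AGR3 by 1.32 ± 0.22 (adjusted p = 0.0080) and on BANP by 1.27 ± 0.22 (adjusted p = 0.0086). It moved down for CYP1B1 (−2.57 ± 0.42, adjusted p = 0.0060), SLC7A5 (−1.92 ± 0.31), TFCP2L1 (−1.79 ± 0.28), PARD6G (−1.79 ± 0.34) and CDH13 (−1.63 ± 0.36, adjusted p = 0.046). Without S4, 1 gene was called in all, and RSRP1 alone of these 10 kept its call. With single libraries left out, CELF4 kept its call in 3 of 16 cases, CDH13 in 5 and PARD6G in 13, and the other 7 in all 16. Among the lists, heat shock genes moved up (adjusted p = 6.03e-05, 0.0548 as an adjusted p with an estimated correlation) and hypoxia genes too (adjusted p = 0.00852, 0.763 as an adjusted p with an estimated correlation). With animal as a block the heat shock change passed with an estimated correlation (adjusted p = 0.0487), but not without the 5-day air library of S1 as well (adjusted p = 0.137). Cell cycle (adjusted p = 1.78e-08, 0.459 as an adjusted p with an estimated correlation) and basal cell genes (adjusted p = 0.00143, 0.0548 as an adjusted p with an estimated correlation) moved down. So did AHR (adjusted p = 0.0242, 0.0719 as an adjusted p with an estimated correlation) and mesenchymal genes (adjusted p = 0.0263, 0.528 as an adjusted p with an estimated correlation). With 1 animal left out, the change for mesenchymal genes kept its call in 1 of 4 cases (adjusted p up to 0.132), that for AHR genes in 2 (up to 0.0587) and that for hypoxia genes in 3 (up to 0.12). The median change for basal cell genes went from −0.765 to −0.494 with the block and without the 5-day air library of S1.

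The series title asks about persistence. Of the 10 genes called at 5 days, 0 were called after recovery, 2 kept their sign, and the median ratio of the log2 fold changes was −0.299. Adjusted over the list alone, 1 of them passed in the same direction and 5 in the opposite one. With animal as a block, 13 of 237 genes called at 5 days were called again in the same direction and 20 in the opposite one. For lower genes the overlap was 11 against 2.55 by chance (Fisher's exact p = 4.85e-05), and for higher genes 2 against 1.42 (Fisher's exact p = 0.655). Overlaps in opposite directions exceeded chance too, with 11 genes higher and then lower against 2.84 (Fisher's exact p = 0.000132) and 9 lower and then higher against 1.27 (Fisher's exact p = 5.16e-06). Fisher's exact test takes genes as independent. Both comparisons come from 1 fit with a shared spread per gene, so a gene with a small spread is called more easily in both. These p-values therefore do not measure persistence. Without the 5-day air library of S1 the overlap with the block was 71 against 46.7 by chance for lower genes and 29 against 36.2 for higher genes, and 142 genes were called in opposite directions. With the block and all libraries, the genes called at both times were ELMO1 and SLC36A4, higher, a number near that by chance. The lower ones with the smallest recovery p were CYP26A1 (log2 −1.05 at 5 days), SHB, TRIB1, FOS and BCL10. Without the 5-day air library of S1, the higher ones with the smallest recovery p were ELMO1, OXNAD1, SLC36A4, PRADC1 and SCGB2A1. The lower ones were then CYP26A1, TBC1D5, NRIP1, PDZRN3 and EPB41L1. From 1 day to 5 days 3 of 4 calls persisted without a block: CYP1B1, HNRNPDL and WDR13. With animal as a block 3 of 11 did, 7 of the 11 kept their sign, and the median ratio of the log2 fold changes was 0.0628. Without the 5-day air library of S1 as well, 45 of 135 were called again in the same direction and 6 in the opposite one.

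Air libraries gave the background of time in culture. From 1 day to 5 days in air 559 genes were called (233 higher, 326 lower), and 2728 with animal as a block. Among the genes that rose most were ANKRD37 at 2.83 ± 0.65, the placental growth factor gene PGF at 2.64 ± 0.71, ADM at 2.52 ± 0.44, PTHLH at 1.94 ± 0.48 and EGLN3 at 1.90 ± 0.45. Among those that fell most was MKI67, going from 789 ± 384 to 60.7 ± 26.1 (log2 −3.66 ± 0.56), with ASPM at −3.55 ± 0.74 and KIF14 at −2.76 ± 0.54. All of these lost their call without S4. Gene lists were not tested over these intervals. Scaling by library totals alone shifted the median gene by −0.143 and gave 890 calls (118 higher, 772 lower), so the balance of directions depends on the scaling. From 5 days to recovery in air 1595 genes were called (826 higher, 769 lower), and 3991 with animal as a block. CYP1B1 rose in air over that week (3.19 ± 0.30), from 42.6 ± 15.4 to 384 ± 59.9, as did SLC7A11 (3.23 ± 0.65), PNLIPRP3 (3.63 ± 0.61) and LRRC4 (2.83 ± 0.36). The multiciliogenesis genes CDC20B (−4.24 ± 0.73), FOXN4 (−3.84 ± 0.61) and CCNO (−3.23 ± 0.60) fell, as did CCKBR (−4.35 ± 0.77) and TESMIN (−3.41 ± 0.80). With 1 animal left out, CCNO kept its call in 3 of 4 cases and TESMIN in 2.

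The 13 other lists did not pass against air at any time without a block. Leaving out the 5-day air library of S1 with animal as a block brought junction genes to an adjusted p = 0.0106 after recovery (0.129 with that library), and among the called lists NRF2 targets at 5 days to 0.000968 (0.285 with it). For the change of the smoke effect it took the AHR list to 0.081 from 5 days to recovery (0.0287 with it). Lower values came for heat shock from 1 to 5 days (adjusted p = 0.0238, 0.112 with it) and squamous genes to recovery (adjusted p = 0.0477, 0.167 with it). With the estimated correlation as well, none of these 5 passed (adjusted p of 0.209 to 0.55). The adjusted p of the other lists at 1 day, 5 days and recovery were 0.634, 0.997 and 0.664 for metallothioneins, 0.896, 0.550 and 0.160 for the unfolded protein and integrated stress response, and 0.178, 0.997 and 0.690 for p53 targets. Inflammatory cytokines gave 0.896, 0.997 and 0.951, with CXCL8 at 0.55 ± 1.40 after 1 day, interferon-stimulated genes 0.896, 0.791 and 0.331, and antimicrobial defence 0.896, 0.923 and 0.417. Goblet cell genes gave 0.896 and 0.561 at 1 and 5 days, and club cell genes 0.896 and 0.384, with SCGB1A1 at 0.08 ± 0.66 after 1 day. Motile cilium genes gave 0.880 and 0.561 at these times, with the ciliated cell regulator FOXJ1 at 0.30 ± 0.49 at 5 days. Rare epithelial cell genes (2 members measured) gave 0.896, 0.384 and 0.631, fibroblast, endothelial and immune cell genes 0.880, 0.969 and 0.550, junction genes 0.896, 0.765 and 0.133, and the DNA methylation machinery 0.134, 0.550 and 0.375. NQO1, both an AHR and an NRF2 target, was at 0.36 ± 0.20, 0.46 ± 0.20 and 0.19 ± 0.20 over the 3 times. Lists called at some times gave, where they did not pass, 0.400 for the AHR list and 0.133 for heat shock after recovery, and 0.108 and 0.304 for cholesterol biosynthesis at 5 days and recovery. Hypoxia gave 0.896 and 0.550 at 1 day and recovery, multiciliogenesis 0.896 and 0.331, cell cycle 0.281 at 1 day and immediate early genes 0.772. Basal cell genes gave 0.742 and 0.561 at 1 and 5 days, mesenchymal genes 0.896 and 0.923, and squamous genes 0.880 and 0.561.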

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

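The tests of gene span and of the label of the 5-day air library of S1, of the scaling and of the luminal cell lists for basal cell genes, of the heat shock list without that library, and all counts of other splits were chosen after the results had been seen.

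The 5-day air library of S1 stood apart from the other 23. The tables argue against low depth, since over the 2316 genes with a mean of at least 1000 its median correlation to the other libraries was still 0.689, against 0.848 for the lowest of the others. A wrong label is argued against by its deviations, whose lowest correlation with its own animal's libraries was 0.303 and whose highest with another animal's was 0.00943, and by CYP1B1 at 35.5 against 148 in the lowest 5-day smoke library. A bias by gene length, as partial degradation of the RNA could give, stays open, as does a biological difference of that culture, which was not tested. Its deviations correlated with gene span at −0.53 (rank correlation across genes, which are not independent replicates), against at most 0.324 in size outside its group and 0.467 within it, where centring on group means mirrors it in part.

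Basal cell genes fell after recovery in every animal (means of −0.468, −0.719, −0.602 and −0.981 on the log2 scale). Gene length is argued against by random lists of the same spans, of which 0% of 10000 had a median as low (lowest −0.382 against −0.561), although fold changes over all genes correlated with span at −0.148. Over all alternatives run, the adjusted p ranged from 4.54e-11 to 0.102, the last being the estimated correlation with the block and without the 5-day air library of S1. A smaller share of basal cells and lower expression in each of them, both possible under smoke, cannot be told apart, because 1 of 3 luminal cell lists was called higher with animal as a block (motile cilium adjusted p = 0.00432, but 0.209 without the block and 0.564 with it and an estimated correlation, goblet 0.637, club 0.813) and counts of cells were not used here. The scaling stays open for the absolute level, because library totals alone shift all genes nearly alike (median gene 0.00834 to 0.0271) and the list is set against the other genes (adjusted p = 4.23e-10).

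As a list, heat shock genes fell in smoke at 1 and 5 days, although its member DNAJB1 was higher at 1 day with animal as a block. Single genes of RNA processing were called too, HNRNPDL at both times and RSRP1, EIF4A2 and HNRNPH3 at 5 days, but no list of such genes was tested. For the heat shock list at 5 days the 5-day air library of S1 as the cause is argued against by an adjusted p of 4.98e-08 with animal as a block and that library left out (4.98e-08 to 0.0466 over all alternatives). Wood smoke and a lower temperature of the smoke-exposed cultures cannot be told apart for these genes, because 0 of 2 cold-inducible genes, CIRBP and RBM3, had a value among the genes tested. Exposure to smoke stays open as the biological explanation, as a hypothesis.

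Single libraries lay far from the 3 others of their group in 13 of 168 groups tested, where chance gives about 1 in 20. In the 5-day air library of S1, depth was 9.45 M reads (12.4 to 12.7 M in the others of its group), the share of mitochondrially encoded genes 8.49% (2.95 to 3.67%) and that of the 10 most abundant genes 18.2% (22.0 to 22.7%), and FKBP4 was at 3290 normalized counts (1800 to 1960). The normalized total was 13.48 M in the 1-day smoke library of S2 against 12.81 to 12.87. CYP1B1 was at 148 normalized counts in the 5-day smoke library of S2 (303 to 334 in the others), WDR13 at 1210 in the 1-day smoke library of S2 (1370 to 1380), and CYP26A1 at 4050 in the recovery smoke library of S2 (1970 to 2110). In recovery air, RSRP1 was at 169 in S2 (230 to 237), EIF4A2 at 3230 in S3 (2530 to 2640) and SAP30 at 83.7 in S4 (50.1 to 54.8). EPHA2 was at 3740 in the 5-day air library of S2 (3250 to 3300) and at 2800 in the recovery smoke library of S3 (3220 to 3240).

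The smoke effect differed between times for 17 gene results, from 23 genes checked for both changes. These 23 were the largest calls of smoke against air in the fit without a block. Choosing genes for an effect in the same libraries favours a difference between times, so the count is no separate support. Over all 14062 genes tested, the smoke effect changed for 2 from 1 day to 5 days and for 49 from 5 days to recovery. From 1 day to 5 days, as differences of log2 fold changes, it moved down for AKAP17A by −1.07 (adjusted p = 0.0457) and for EPHA2 by −0.748 (adjusted p = 0.00843). From 5 days to recovery it moved down for CYP1B1 by −2.57 (adjusted p = 0.00599), HNRNPDL by −1.08 (0.0214), WDR13 by −0.772 (0.0401), TFCP2L1 by −1.79 (0.00572), CDH13 by −1.63 (0.0459), SLC7A5 by −1.92 (0.00599) and SIPA1L2 by −1.49 (0.0207). It moved up for RSRP1 by 2.44 (adjusted p = 0.000304), FKBP4 by 1.25 (0.00572), EIF4A2 by 1.01 (0.00351), HNRNPH3 by 0.66 (0.021), NKTR by 0.971 (0.00599), EPHA2 by 0.641 (0.00703), SAP30 by 2 (0.00599) and AGR3 by 1.32 (0.00804). For CYP1B1 the level in air also rose from 42.6 to 384 normalized counts over that interval.

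Other splits of the libraries into groups of the same sizes were fitted for each count of calls, and the real split was compared with those that, like it, part the libraries of every animal. For a comparison of 2 groups these splits number 8, too few for a share under 0.05. The real split gave 4, 10 and 34 calls at 1 day, 5 days and recovery, and 559 and 1595 in air over the 2 intervals, against 0 in each case for the highest of the other 7, and with animal as a block 11, 237 and 480 calls at the 3 times against 0 (1 of 8 splits with as many in each). Splits that leave libraries of an animal together differ in that they keep differences between animals in the contrast. They gave at most 0, 17, 0, 0 and 7 calls in the same order, the 17 from one that put the 5-day air library of S1 with 3 smoke libraries. For the change of the smoke effect from 5 days to recovery there were 49 calls against 14 for the highest other (1 of 100 splits with as many). These splits were drawn from those possible, and swapping smoke and air within animals also puts the smoke effect into the spread. They therefore cannot exclude chance, and without S4 the count was 1. For the change from 1 day to 5 days, 3 of 100 splits gave as many calls, a share under 0.05. The highest other equals the real count of 2, and without S2, S3 or S4 the count was 0, so it rests on few calls.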

How the results depend on the processing

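The pseudocounts, quantile normalization, the fit without a variance trend, array weights, the block joined to an estimated correlation or to leaving out the 5-day air library of S1, and matching by either symbol were chosen after the data had been seen. The alternatives fixed in advance that need whole counts (edgeR, DESeq2, voom and DESeq2 size factors) were not run, because the values are not counts. Counts of calls follow in the order 1 day, 5 days, recovery, change from 1 to 5 days, change from 5 days to recovery, air from 1 to 5 days and air from 5 days to recovery, and were 4, 10, 34, 2, 49, 559 and 1595 in the fit without a block. Within 1.5 times of these lay all counts with pseudocounts of 0.5 and 5 and with the stricter filter. With the block they were 11, 237, 480, 6, 501, 2728 and 3991, and with the block as a random effect 11, 179, 330, 5, 405, 2583 and 3772. They were, with array weights and the block 735, 1133, 2296, 195, 1927, 4038 and 4390, and with the block and without the 5-day air library of S1 135, 880, 2639, 43, 1583, 2622 and 3806. Removal of differences between animals is what the block does, and leaving out that library lowers the pooled spread (median SE with the block at recovery 0.186 with it and 0.119 without it, median size of the log2 fold change 0.187 in both). Why array weights call more was not tested. Fitting only the libraries of a comparison gave 1, 0, 6, 0, 1, 0 and 16, with fewer libraries to set the spread, and with the block 1281, 0, 2650, 5, 73, 0 and 4. The 2 of these with many calls, at 1 day and recovery, do not contain the 5-day air library of S1, and all the others do. Whether that library accounts for the contrast was not tested in this fit. An added log2 fold change of 1, which can only remove calls, gave 1, 2, 16, 1, 23, 191 and 408, and an adjusted p under 0.1, which can only add them, gave 5, 35, 62, 4, 111, 1571 and 2776. Library totals alone gave 1 at 1 day, 0 for the change from 1 to 5 days and 890 for air from 1 to 5 days. No filter gave 1 and 25 for the 2 changes and 350 for air from 1 to 5 days, quantile normalization gave 6 at 5 days and 1 for the change from 1 to 5 days, and no variance trend gave 2 at 1 day and 1 for that change. In these 3 and with totals alone the cause was not tested. With 1 library of the comparison or 1 animal left out, which leaves fewer libraries to test, the lowest and highest counts were 1 and 8 (without S1) at 1 day, 2 (without S4) and 53 (without the air library of S1) at 5 days, and 0 (without S4) and 476 (without S1) after recovery. They were 0 and 3 for the change from 1 to 5 days, 1 (without S4) and 169 (without the 5-day air library of S1) for that to recovery, 10 (without S4) and 1475 (without the 5-day air library of S3) for air from 1 to 5 days, and 296 (without S4) and 2468 (without the 5-day air library of S3) for air to recovery. Without a block, leaving out the 5-day air library of S1, which is in neither comparison, gave 15 at 1 day and 352 after recovery. Of the libraries in a comparison, those that moved a count by over 1.5 times were all at 1 day except the smoke library of S2, the air library of S1 and the smoke libraries of S1 and S4 (6 each) at 5 days, and all 8 at recovery (2 to 88). For air from 1 to 5 days they also include the 1-day libraries of S1, S3 and S4 (104, 187 and 173) and the 5-day library of S4 (1079), and for air to recovery the 4 recovery libraries (811 to 977). For the change to recovery they also include, in air at 5 days, S2 (29) and S3 (91), in smoke at 5 days, S1 (17) and S4 (19), all 4 in recovery air (21 to 29), and in recovery smoke S1 (116), S2 (27) and S4 (18). For the change from 1 to 5 days 11 of 16 single omissions left 1 call, and 1 gave 3. Calls at 5 days repeated after recovery numbered 0 without a block, 13 with it, 100 with it and without the 5-day air library of S1, and 1 with p adjusted over the list alone, and the cause was not tested.

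Lists called numbered 4, 6, 5, 4 and 6 for the 3 times and the 2 changes. With an estimated correlation, which allows for members that vary together, they were 3, 1, 1, 0 and 0, with the block added 4, 1, 2, 0 and 1, and without the 5-day air library of S1 as well 3, 1, 0, 0 and 0. Without 1 animal they ranged from 4 to 4, 2 to 6, 5 to 6, 1 to 4 and 3 to 6, the lowest of the 5-day list and of both changes being without S3. With the block all 25 list calls were kept, with totals alone 24, and with either symbol all 25. Of 140 results of single genes, 140 stayed on their side of the threshold with a pseudocount of 0.5 and with the stricter filter, 139 with a pseudocount of 5, 135 with quantile normalization, 134 without a variance trend, 133 without a filter and 130 with totals alone. With the block 80 did and the other 60 gained a call. With only the libraries of the comparison 52 of 140 lost theirs, and with the block in that fit 29 lost and 45 gained one. Over the fits with 1 library or animal left out, 285 values lost a call, 33 gained one and 1 without a call moved (HMOX1 after recovery). No named gene result with a call, and no called list, reversed its direction under the alternatives run for it. Values without a call could change sign, as that of HMOX1 after recovery did. For library measures, exact sign flips by animal give no p under 0.125 and so say nothing about stability. On simulated changes of 2-fold, 44 to 50% were recovered without a block and 61 to 69% with it, so a gene without a call at this depth and number of animals may have changed by that much (11, 237 and 480 calls with the block).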

Other observations

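The genes named here were noticed after their values had been seen, and both list tests were chosen before the values of the members they use had been seen. They leave out the members that had been noticed.

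A lower response to retinoic acid in smoke than in air after recovery is a hypothesis drawn from CYP26A1. Retinoic acid induces this gene, and it was lower in smoke (log2 −1.76, lower in 4 of 4 animals), although its level lay above that at 5 days under both exposures. Under the block CYP26B1 (log2 −3.21, adjusted p = 0.0303, from 262 ± 52.2 normalized counts in air to 34.2 ± 24.4 in smoke, SD, n = 4), RARB (−1.35, adjusted p = 0.0255, 838 to 328) and NRIP1 (−1.26, adjusted p = 0.0267, 2260 to 948) were also lower in smoke, each in 4 of 4 animals. None of these 3 passed without a block. Of 10 other retinoic acid response genes with a value, 7 were below 0 (mean log2 −0.217 ± 0.412 SD). For these 10, limma camera with animal as a block gave an adjusted p = 0.0313 over 2 lists, with 0.0313 before adjustment too. Before adjustment it gave 0.055 without a block, 0.234 with an estimated correlation and 0.195 with both. The values are consistent with a lower response. They may rest on the members noticed first, and they leave open a change in the cells that carry the response. The supply of retinoic acid from the medium was not tested.

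Endoplasmic reticulum chaperone genes gave a second hypothesis after recovery. In the fit with the block HSPA5 (log2 0.76, adjusted p = 0.0017, 11100 ± 1930 in air to 18700 ± 2910 in smoke, SD, n = 4), MANF (0.78, adjusted p = 0.0018), HYOU1 (0.53, adjusted p = 0.0036) and CRELD2 (0.95, adjusted p = 0.017) rose, each in 4 of 4 animals, and none passed without a block. Of 15 other folding genes with a value 13 were above 0 (mean log2 0.204 ± 0.227 SD), among them DNAJB11 (0.46, adjusted p = 0.0071 with animal as a block) and HSP90B1 (0.44, adjusted p = 0.038 with animal as a block). For these 15, limma camera with animal as a block gave an adjusted p = 0.002 over 2 lists. Before adjustment it gave 0.001 with the block, 0.000467 without it, 0.0517 with an estimated correlation and 0.0361 with both. A chaperone response of the endoplasmic reticulum a week after smoke may underlie the higher values after recovery. At 5 days the genes named here lay below 0 (HSPA5 −0.36, MANF −0.36, HYOU1 −0.32, CRELD2 −0.88, DNAJB11 −0.14 and HSP90B1 −0.42). Of these only CRELD2 passed at 5 days with animal as a block (adjusted p = 0.0411), and other folding genes lay on both sides of 0. The list fixed in advance for the unfolded protein and integrated stress response did not pass (adjusted p = 0.160).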
